A study of Mus musculus with 6 samples.

How the data were processed

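RNA from 6 mammary tumours was extracted with Trizol, cleaned up on columns, converted to biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The samples were grouped by their transgene label into 3 PyMT control and 3 PyMT/ETP tumours, all from 12-week-old females of one strain. The deposited values are probe intensity values on a linear scale, 1 for each of 45281 probes and 6 arrays. The software, the background treatment and the normalization between arrays are not given in the sources used here. The deposited intensity values of the 6 arrays, when sorted, differed by at most 0.15, so they had been made equal between arrays, as quantile normalization does. On every array the lowest was 68.3, the median 96.5 and the highest 35836, so a background pedestal was still in them. A second table, with values from before normalization, was not used here: its 24 value columns carry only a chip and a position, and no label pairs these with samples. Chip and position were not tested as batches.

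Before the data were examined, the plan was to start from values before normalization with their detection p-values. Because those columns could not be paired with samples, the background was estimated from the deposited values instead, before any comparison of groups was fitted. Its level, 86.1, was the mode of the lowest 60% of the values of all 6 arrays pooled. Its SD, 4.83, was taken from the values below that mode. Values were corrected with limma's normexp model with those parameters, an offset of 16 was added and log2 was taken, so fold changes of dim genes are understated. Probes above 94, the 5% limit of that background, on at least 3 of the 6 arrays were tested, which left 24889 probes and 12863 genes. A stricter limit, 97.3 on all 6 arrays, left 17358 probes and 9880 genes. No detection p-values were used, and the limit rests on the shape of the low values.

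Probe names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. The gene identifiers of 34807 probes were found in the RefSeq gene table, which gave the symbols. Each gene was represented by its tested probe with the highest mean log2 value. A group whose arrays were all at or below the background limit has only a bound, which was computed against the higher of the limit, 4.61 log2 units, and the probe's own value.

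Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, 1 factor), with Benjamini-Hochberg adjustment over probes or genes and a threshold of 0.05. The prior had 4.49 degrees of freedom. The 26 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 3 measured members. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time. It took the collagen VI chains, then for each direction the 12 genes of largest change that passed with non-overlapping groups. Where fewer passed, it was filled with the genes of smallest unadjusted p among those with a fold change of at least 1.5 and non-overlapping groups, leaving out symbols of unnamed transcripts, of which it met 0. It also took up to 4 members of each list with the smallest unadjusted p. No gene passed, so all 24 of the second kind were filled in this way. Genes named outside the rule are said to be so.

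The fit was tested on simulated data. In 20 draws of the 12863 genes, with 200 genes changed, the comparison of PyMT/ETP with PyMT control recovered 60.5% of genes changed 2-fold, 97.5% of those changed 4-fold, 99.2% of those changed 8-fold and 100% of those changed 16-fold. On average 4.2% of the calls were false. These draws used independent genes, with normal noise and SDs drawn from the fitted prior. The simulated folds were added on the log2 scale after the offset. The recovery therefore does not carry over to dim genes, whose fold changes the offset understates, or to genes that vary widely within a group. In the real data Prr9 and Crct1, named here after their values were seen, were by group means 13.6-fold and 11.1-fold lower in PyMT/ETP tumours. These folds came from PyMT control replicates 2 and 3. Prr9 was at 10.00 and 10.73 there and at 4.54 in replicate 1, against at most 4.905 in PyMT/ETP tumours. Crct1 was at 9.12 and 10.55 there and at 5.67 in replicate 1, against at most 5.55. Their SDs in control tumours were 3.39 and 2.51 log2 units, and both had an adjusted p of 0.997 in limma's test. With no effect and independent genes, camera at the preset correlation called 0.05 lists on average. With no effect and an assumed correlation of 0.3 between members of a list, it called 4.15 lists on average and up to 9. With the estimated correlation it then called 0. With the preset correlation and independent genes, a shift of 0.5 log2 units of the macrophage list was called in all 20 draws. No shift was simulated for the estimated correlation or for fry, so what those tests can detect here is not known. In the real data, 17 of the 26 lists had an estimated correlation over 0.1.

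The alternatives were no background correction, an offset of 50, cyclic loess, no low-value filter, the stricter limit, an intensity trend with a robust prior, array weights, the replicate number as a block, each array left out, the mean of all probes of a gene, another threshold and both other list tests. Added after the data were seen were no background correction together with the stricter limit, the either-direction test of the epithelial list under each setting, both other list tests under each setting, and the fit without PyMT control replicates 2 and 3. Lists for sebaceous gland, melanocytes and the hair shaft with inner root sheath were written after the groups had been compared.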

Results

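Gene expression was measured in mammary tumours of 12-week-old female mice of the FVB strain that carried the PyMT transgene, in which a mouse mammary tumour virus promoter drives the polyomavirus middle T antigen in mammary epithelium. The 6 Illumina arrays held 3 PyMT control tumours and 3 PyMT/ETP tumours, which also carried an endotrophin transgene. Endotrophin is the carboxy-terminal fragment cleaved from the collagen VI alpha 3 chain. The comparison asked which transcripts differ between tumours with and without the endotrophin transgene. The labels do not say that each array came from a separate mouse, so the p-values measure the spread between these samples. On each array, 54.6% or 54.7% of the 45281 probes lay above the background limit. These shares are alike because the deposited values had been made equal between arrays, so they do not measure array quality. The number of arrays limits the precision. None of the named probes was assigned to Col6a3, so nothing here checks the transgene.

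No gene passed the test between PyMT/ETP and PyMT control tumours. With limma and Benjamini-Hochberg adjustment, 0 of 24889 probes and 0 of 12863 genes passed adjusted p 0.05, and the lowest adjusted p for a gene was 0.997. At unadjusted p 0.05 there were 555 genes, 293 of them higher in PyMT/ETP, where 643 would be met by chance. With 1 array left out there were 401 to 805, with 805 without PyMT control replicate 1 and 665 without PyMT/ETP replicate 3. The groups did not overlap for 1051 genes, or 8.2%, against 10% by chance. The median 95% confidence interval of a gene reached 0.39 log2 units, or 1.31-fold, to either side. Without PyMT control replicate 1, 16 genes passed, all lower in PyMT/ETP, and each of them was highest in PyMT control replicates 2 and 3. They included the hair keratins Krt34, Krt71, Krt73 and Krt86 and the hair cuticle gene S100a3, named here after their values were seen. Without PyMT control replicates 2 and 3, an alternative added after the data were seen, 1 gene passed. This was B4galnt2, a glycosyltransferase gene, at 9.47 in PyMT control replicate 1 and between 4.35 and 5.31 in the other 5 arrays.

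By their brightest probes, the collagen VI chains Col6a1 and Col6a2 differed between the groups by less than the spread between replicates. Col6a1 was at 10.28 ± 0.30 log2 units in PyMT control and 10.30 ± 0.38 in PyMT/ETP tumours (SD, n = 3), a log2 difference of 0.02 (SE 0.23). Col6a2 was at 8.01 ± 0.26 and 7.99 ± 0.29 (SD, n = 3), a log2 difference of -0.02 (SE 0.20). A dimmer Col6a2 probe gave a log2 difference of -0.42, larger than the SD of either group (0.38 and 0.23), and did not pass, and a dimmer Col6a1 probe gave 0.30. Col6a4, Col6a5 and Col6a6 were below the filter and were not tested. Basement membrane genes went both ways: the laminin chain Lamb2 had a log2 difference of 0.41 and the type IV collagen chains Col4a2 and Col4a1 had -0.39 and -0.30, none of which passed.

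**Figure D1:**
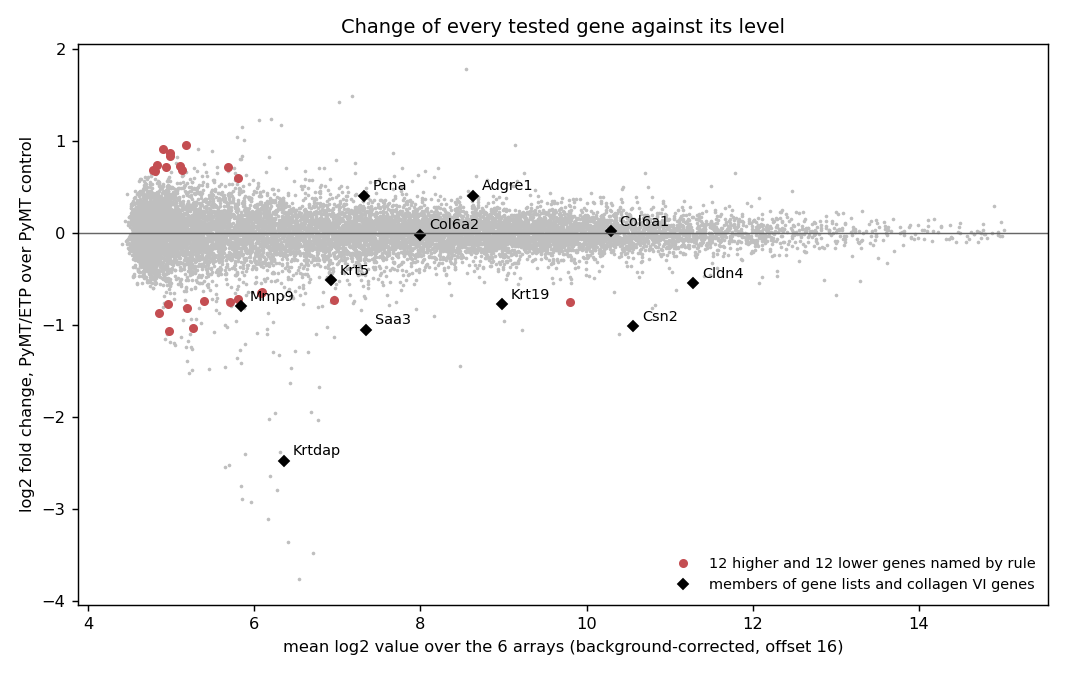
Log2 fold change of PyMT/ETP over PyMT control against the mean log2 value over the 6 arrays, for the 12863 genes tested. Grey points are genes, red points the 12 higher and 12 lower genes named by the rule, and black diamonds members of gene lists and the collagen VI genes. Col6a1 and Col6a2 lie at 0.02 and -0.02, and Krtdap lies at -2.48.

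The genes nearest to the threshold had small differences, and most of the higher ones were close to background. None passed, with an adjusted p of 0.997 in limma's test. A fold change of at least 1.5 with non-overlapping groups was seen for 41 higher and 53 lower genes. The rule named the 12 of smallest unadjusted p in each direction. Leaving out symbols of unnamed transcripts, 13 higher and 29 lower genes of this kind were above the stricter background limit on all 6 arrays. Of the 12 higher genes named by the rule, only Xrn1 and Relch were above it. Xrn1, a cytoplasmic exoribonuclease, had a log2 difference of 0.72 (SE 0.15), and Relch one of 0.60 (SE 0.13), a sign that its other tested probe did not share. Tafa5 (0.96), Trmt12 (0.88), Ift122 (0.73), Otos (0.72), Tns2 (0.69) and Fgf15 (0.68) were dim. Phex, Rab40b, Fyn and Aldh1a7 were not above background in any control tumour. Against that limit they were at least 1.68-fold, 1.51-fold, 1.45-fold and 1.74-fold higher in PyMT/ETP tumours. Among the 12 lower genes, the brightest was Denn2b, at 10.18 ± 0.30 in control and 9.43 ± 0.21 in PyMT/ETP tumours (SD, n = 3). Tgm1, the transglutaminase of the cornified envelope, had a log2 difference of -0.73. The log2 differences were -0.75 for Gsg1l, -0.72 for Gchfr, -0.73 for Ccdc25, -0.65 for Frat2 and -0.64 for Rbm10. Acp7 (-1.03), Aire (-0.82) and Kcnab3 (-0.77) were dimmer. Tfap2e and the keratin Krt42 were not above background in any PyMT/ETP tumour, and were at least 1.6-fold and 1.86-fold higher in control tumours.

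Of 26 gene lists, limma's camera with its preset correlation called 4, all of which had an adjusted p of 0.795 with an estimated correlation. Genes of skin keratinocytes and of basal and myoepithelial cells and genes for matrix proteases were lower in PyMT/ETP tumours, and macrophage genes were higher. In no list did a member pass over all genes. With fry, which tests whether the members move one way on balance, no list passed, and the lowest adjusted p was 0.584. Under the other settings and with arrays left out, camera with an estimated correlation called 0 lists, with a lowest adjusted p of 0.592, and fry called 0, with a lowest adjusted p of 0.256. Leaving out a single array shrank the difference by over 1.5 times, or turned its sign, for 85 of the 129 named genes and for the medians of all 26 lists. With 3 tumours against 3, an exact permutation test cannot go below 0.1.

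Skin keratinocyte genes had a median log2 difference of -0.81 over 5 measured members, 4 of them negative (camera adjusted p = 0.0101). Krtdap, a gene of differentiating keratinocytes, was at 7.60 ± 1.75 in control and 5.12 ± 0.80 in PyMT/ETP tumours (SD, n = 3). Lor, a cornified envelope protein, had a log2 difference of -0.81, Krt10 one of -0.96 and Sbsn one of -0.39. Adjusted over the list alone, 2 members passed, Krtdap and Lor, with a lowest adjusted p of 0.0496 in limma's test. The mean deviation of the list was 1.29 in PyMT control replicate 3, against 0.15 and -0.14 in the other control tumours, and without that array the camera adjusted p was 0.0803. Over the other settings it ran from 0.000232 to 0.18, the highest above the stricter background limit. The median was -0.36 without PyMT control replicate 3, -0.28 without background correction, -0.39 at the stricter limit and -0.25 without PyMT control replicates 2 and 3. Without PyMT control replicate 3, Krtdap was at -1.55, Krt10 at -0.36 and Sbsn at -0.17, and without replicate 2 Lor was at -0.48.

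Basal and myoepithelial genes had a median log2 difference of -0.34, with 7 of 10 members negative (camera adjusted p = 0.0366). The basal keratins Krt5, Krt14 and Krt17 had log2 differences of -0.51 (SE 0.19), -0.46 (SE 0.25) and -1.10 (SE 0.48), and the transcription factor Trp63 one of -0.31. Adjusted over the list alone, 0 members passed, the lowest being 0.251. The list was highest in PyMT control replicate 3 (mean deviation 0.36), as was the skin keratinocyte list. The camera adjusted p was 0.245 without that array, 0.0938 without PyMT/ETP replicate 1, 0.366 without PyMT/ETP replicate 3 and 0.153 with array weights, and ran from 0.000107 to 0.762 over the other settings. With 1 array left out the median ran from -0.47 to -0.19, the latter without PyMT/ETP replicate 3. Without PyMT control replicates 2 and 3 it was -0.11, and Krt17 was at 0.19. Trp63 was at -0.058 without PyMT control replicate 3.

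Matrix protease and inhibitor genes had a median log2 difference of -0.20, with 13 of 17 members negative (camera adjusted p = 0.0409). The gelatinase Mmp9 was at 6.23 ± 0.41 in control and 5.44 ± 0.45 in PyMT/ETP tumours (SD, n = 3). The urokinase receptor gene Plaur had a log2 difference of -0.70, Mmp10 one of -0.74 and Plat one of -0.32. Adjusted over the list alone, 0 members passed, the lowest being 0.273. The camera adjusted p was 0.595 without PyMT control replicate 2, 0.0679 without PyMT/ETP replicate 2, 0.535 without PyMT/ETP replicate 3 and 0.0569 with no low-value filter, and ran from 0.000506 to 0.595 over the other settings. The median was -0.016 without PyMT control replicate 2 and -0.028 without PyMT/ETP replicate 3, and reached -0.38 without PyMT control replicate 3. Mmp10 was at -0.28 without PyMT control replicate 2.

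Macrophage genes had a median log2 difference of 0.14, with 14 of 17 members positive (camera adjusted p = 0.0366). Adgre1, which encodes the F4/80 antigen, was at 8.43 ± 0.16 in control and 8.84 ± 0.25 in PyMT/ETP tumours (SD, n = 3), with non-overlapping groups. Adgre1 was named for its small p, which favours non-overlap, seen for 8.2% of all genes. The log2 differences were 0.33 for Mpeg1, 0.29 for Lyz2 and 0.24 for Csf1r, and the other Mpeg1 probe had the opposite sign. Adjusted over the list alone, 0 members passed, the lowest being 0.518. The mean deviation of the list was 0.26 in PyMT/ETP replicate 1, against 0.03 and -0.09 in the other PyMT/ETP tumours, and without that array the camera adjusted p was 0.479. It was 0.120 without PyMT control replicate 1, 0.133 without PyMT control replicate 3 and 0.0633 with the mean of all probes of a gene, and ran from 0.0016 to 0.479 over the other settings. With 1 array left out the median ran from 0.050, without PyMT/ETP replicate 1, to 0.22.

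**Figure D2:**
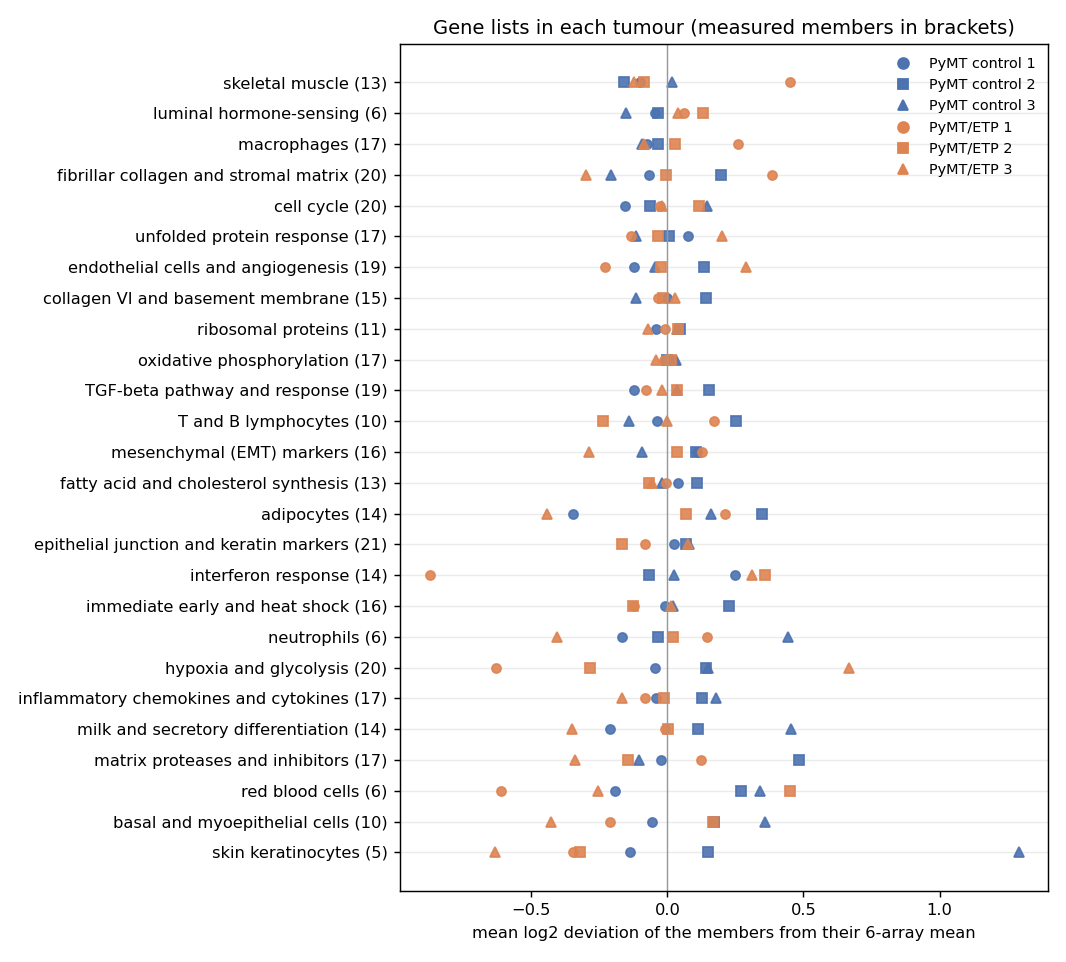
Mean log2 deviation of the measured members of each of the 26 gene lists from their mean over the 6 arrays, with 1 point for each tumour (blue, PyMT control; orange, PyMT/ETP; circle, square and triangle, replicates 1, 2 and 3). The skin keratinocyte list lies at 1.29 in PyMT control replicate 3, and the interferon list at -0.87 in PyMT/ETP replicate 1.

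Epithelial junction and keratin genes went both ways. The camera adjusted p was 0.13 for a median log2 difference of -0.11 over 21 members, while fry's test for change in either direction gave an adjusted p of 0.0442, the only list it called. The simple-epithelium keratin Krt19 was at 9.37 ± 0.51 in control and 8.59 ± 0.13 in PyMT/ETP tumours (SD, n = 3). Among the controls, Krt19 was at 8.78 in replicate 1 and at 9.71 and 9.60 in replicates 2 and 3, against at most 8.67 in PyMT/ETP tumours. The tight junction genes Cldn4 and Ocln had log2 differences of -0.54 and -0.38, and the adhesion molecule Epcam one of 0.41, each with non-overlapping groups. Members were named for their small p, which favours non-overlap, seen for 8.2% of all genes. Epcam was low, at 5.26 in control and 5.67 in PyMT/ETP tumours, against 11.56 and 11.01 for Cldn4. Of the 21 members, 14 were negative and 7 positive. Adjusted over the list alone, 0 members passed, the lowest being 0.144. Of 17 other settings, 5 kept this call, among them the intensity trend, which does not enter the test, and the adjusted p ran from 0.0202 to 1. It was 0.461 and 0.654 without PyMT control replicates 2 and 3, 0.312 and 0.946 without PyMT/ETP replicates 1 and 2, 0.0503 without PyMT/ETP replicate 3, 0.195 without background correction, 0.126 with offset 50, 0.0551 with cyclic loess, 0.459 with the replicate block, 0.188 with the mean of all probes, 0.234 without background correction at the stricter limit and 1 without PyMT control replicates 2 and 3. The camera adjusted p ran from 0.0148 without PyMT/ETP replicate 3 (0.608 with an estimated correlation) to 0.636, and 3 of 17 other settings called the list at the preset correlation.

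Stromal, mesenchymal and signalling lists were not called with all 6 arrays. The median log2 difference was 0.07 for fibrillar collagen and stromal matrix (camera adjusted p = 0.526), where Fbln2 had a difference of 0.30 and Col1a2 one of 0.36. It was -0.01 for collagen VI and basement membrane (0.782), -0.06 for mesenchymal markers (0.443), -0.06 for the TGF-beta pathway (0.847) and 0.04 for endothelial genes (0.526). Itga5, the fibronectin receptor chain, had a difference of -0.64 that its other probe did not share, and Twist1 had -0.34. In the TGF-beta list, Id2 had a log2 difference of 0.33 and Id1 one of -0.42. The endothelial transcription factor Sox17 had one of 0.34. Without PyMT/ETP replicate 3, the fibrillar collagen list was called at the preset correlation, with a median of 0.27 and an adjusted p of 0.00518 (adjusted p = 0.866 with an estimated correlation), in a range up to 0.756 over the other settings.

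Immune lists other than macrophages were not called under the main settings. The median log2 difference was -0.17 for neutrophil genes (camera adjusted p = 0.526), -0.04 for T and B lymphocyte genes (0.526), -0.10 for chemokines and cytokines (0.179) and -0.14 for interferon response genes (0.276). The acute-phase genes Saa1, Saa2 and Saa3 had log2 differences of -0.67, -0.84 and -1.05, the last with an SE of 0.52, and -0.30, -0.44 and -0.37 without PyMT control replicate 3. Of the 17 measured members of their list, 12 were negative and 5 positive, among the latter the dim Ccl3 at 0.37. Of the 6 measured members of the neutrophil list, 3 were negative and 3 positive. The negative ones, S100a8, S100a9 and Ltf, had -0.54, -0.39 and -0.52, and Ltf is also in the milk and secretory list. Among the positive ones, Elane had 0.32 and was dim. Without PyMT control replicate 3, S100a8 and S100a9 had -0.078 and -0.12, and without PyMT/ETP replicate 3, Ltf had -0.14. Isg15 had -0.51, or -0.096 without PyMT/ETP replicate 1, and was at 6.88 in PyMT/ETP replicate 1 and between 8.02 and 8.46 in the other 5 tumours. Of the 14 measured interferon genes, 11 were negative and 3 positive. Among the latter, Zbp1 had 0.36, a sign that 1 of its 2 other probes shared. At the stricter background limit the neutrophil list was called at the preset correlation, with a median of -0.52 and an adjusted p of 0.0356 (adjusted p = 0.716 with an estimated correlation), in a range up to 0.797 over the other settings. It was also called without background correction at that limit (0.0390, and 0.671 with an estimated correlation). That limit left out Elane and kept the negative members S100a8, S100a9 and Ltf, and the median of -0.52 was the value of Ltf. The interferon list was called without PyMT/ETP replicate 1, with a median of 0.32, and without replicates 2 or 3, with medians of -0.39 and -0.35 (camera adjusted p = 0.000506, 0.00558 and 0.0193, and 0.676, 0.685 and 0.866 with an estimated correlation). Its camera adjusted p ran up to 0.842 over the other settings.

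Among the epithelial and metabolic lists, the median log2 difference was 0.02 for cell cycle genes (camera adjusted p = 0.455). The replication genes Pcna, Tyms and Mcm3 had differences of 0.41, 0.37 and 0.37, each with non-overlapping groups, and Ccne1 had -0.35. These genes were named for their small p, which favours non-overlap, seen for 8.2% of all genes. Without PyMT control replicate 3 the cell cycle list was called, with a median of 0.11 and a camera adjusted p of 0.0369 (adjusted p = 0.817 with an estimated correlation), in a range up to 0.969 over the other settings. It was also called without PyMT control replicates 2 and 3 (0.0494, and 0.949 with an estimated correlation). The median was -0.08 for milk and secretory genes (0.179), where Csn2 and Csn1s1 had differences of -1.01 (SE 0.66) and -0.81 (SE 0.56), or -0.10 and -0.042 without PyMT control replicate 3, 0.12 for luminal hormone-sensing genes (0.217) and -0.15 for hypoxia and glycolysis (0.179). The estrogen receptor gene Esr1 and its cofactor gene Foxa1 had 0.43 and 0.33, and the other Esr1 probe had the opposite sign. At the stricter background limit the luminal median was 0.033. Foxa1 was near background, at 4.71 in control and 5.05 in PyMT/ETP tumours. The median was -0.05 for oxidative phosphorylation (0.526), -0.10 for fatty acid and cholesterol synthesis (0.179), 0.05 for the unfolded protein response (0.714) and -0.10 for immediate early and heat shock genes (0.0751). Egr2 and Atf3 had log2 differences of -0.71 and -0.60. Egr2 was at 6.98 in PyMT control replicate 1 and at 7.86 and 8.22 in replicates 2 and 3, against a mean of 6.98 in PyMT/ETP tumours. The immediate early list was called at the preset correlation under 9 of 17 other settings, among them no background correction (0.0394), offset 50 (0.0349) and the fits without PyMT control replicate 1 (0.0342), PyMT control replicate 3 (0.0348) or PyMT/ETP replicate 3 (0.0148). Its camera adjusted p ran up to 0.552 over these settings, and with an estimated correlation the lowest was 0.671. Without PyMT/ETP replicate 3 the hypoxia list was called, with a median of -0.39 and a camera adjusted p of 3.31e-11 (adjusted p = 0.608 with an estimated correlation), in a range up to 0.864 over the other settings. With all 6 arrays it was also called with array weights (0.0450) and with the replicate block (0.0347), at 0.902 and 0.792 with an estimated correlation. Ribosomal protein genes, which were bright and even, had a median of -0.03 (0.564).

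For other tissues that a tumour sample can hold, the median log2 difference was 0.29 for skeletal muscle (camera adjusted p = 0.254), -0.10 for adipocytes (0.407) and -0.23 for red blood cells (0.0809). All 6 red blood cell genes were negative, among them Hba-a1 at -0.47 and Hbb-bs at -0.42. With 1 array left out, the red blood cell median ran from -0.52 without PyMT/ETP replicate 2 (camera adjusted p = 1.77e-06, and 0.592 with an estimated correlation) to -0.0045 without PyMT/ETP replicate 1, and it was 0.016 without PyMT control replicates 2 and 3. At the preset correlation, 5 of 17 other settings called the list. One of them was the fit without PyMT control replicate 1 (camera adjusted p = 0.028, and 0.787 with an estimated correlation), and the adjusted p ran up to 0.863 over these settings. Without PyMT control replicate 1 the adipocyte list had a median of -0.27 and a camera adjusted p of 0.0342 (adjusted p = 0.787 with an estimated correlation), in a range up to 0.786 over the other settings. With the mean of all probes the skeletal muscle list had a camera adjusted p of 0.0487 (0.790 with an estimated correlation), in a range up to 0.602 over the other settings. The beta-globin genes are near-identical copies, and their probes may not tell them apart.

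**Figure D3:**
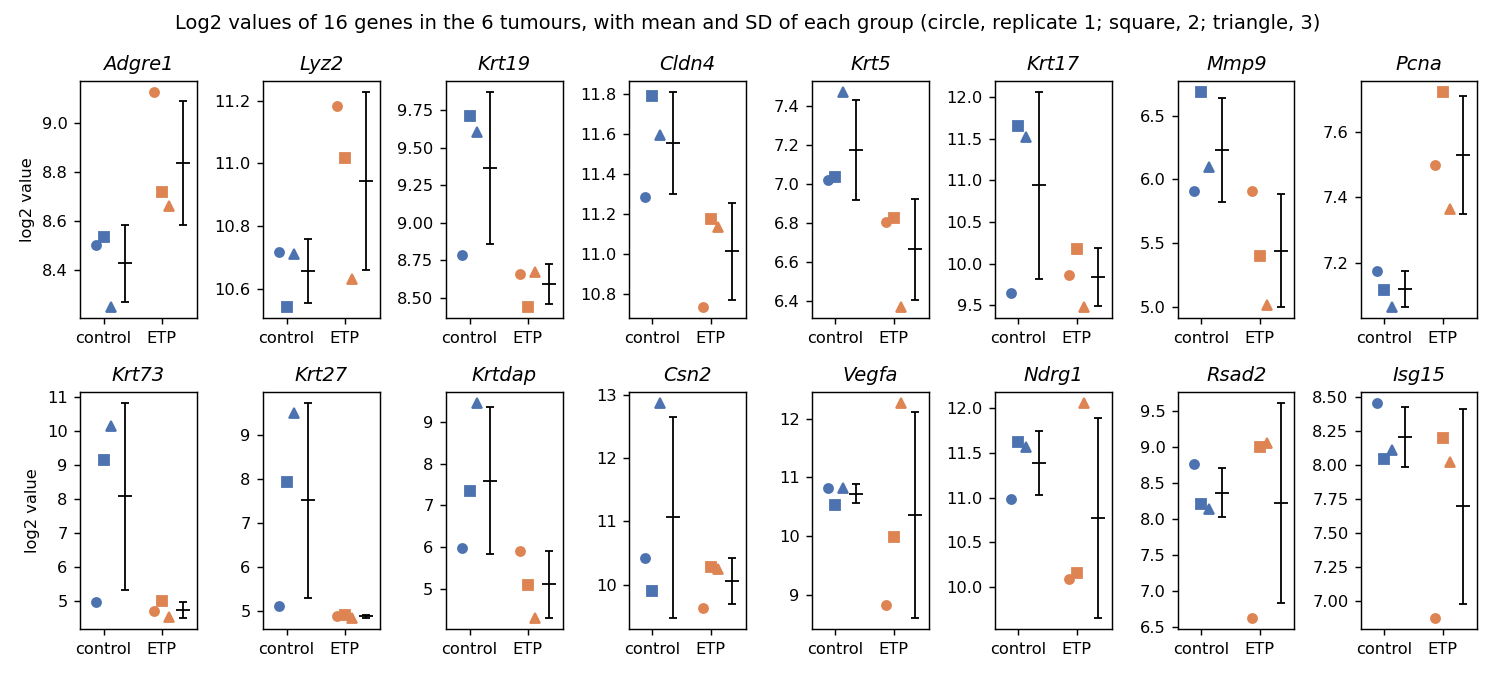
Log2 values of 16 genes in the 6 tumours (blue, PyMT control; orange, PyMT/ETP; circle, square and triangle, replicates 1, 2 and 3), with the mean and SD of each group of 3 in black. Adgre1 and Pcna lie higher in all 3 PyMT/ETP tumours and Krt19, Cldn4, Krt5 and Mmp9 lower, and the lower row holds 8 genes that differ widely between tumours of one group.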

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

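Tests without PyMT control replicates 2 and 3, those without background correction at the stricter limit, the settings of the epithelial list's either-direction test and the estimated correlation or fry under other settings were chosen after the data were seen. The count of genes past adjusted p 0.05 stayed at 0 under the planned settings with all 6 arrays, and leaving out 1 array gave 0 to 16 genes and 0 to 18 probes, the highest without PyMT control replicate 1. Without PyMT control replicates 2 and 3, it was 1 probe and 1 gene, and the lone control is assumed to vary like the other group. Genes at unadjusted p 0.05 numbered 362 at the stricter limit and 304 without background correction as well, where fewer genes were tested. The number of gene lists called, 4, became 7 with the replicate block, 7 with the mean of all probes, 0 with an estimated correlation, 0 with fry and 1 without PyMT control replicates 2 and 3. It was 3 to 7 with 1 array left out. With an estimated correlation or fry it was 0 under each of these settings. The intensity trend does not enter the list tests. The cause was not tested. No label pairs same-numbered tumours, so the replicate block is not known to be a pairing. Their deviations had correlations of -0.065, -0.059 and -0.109. With 3 arrays in each group these values are bound to one another, and they cannot tell whether a chip, day or litter was shared. The block left the count of genes at 0. Median scaling was not run, because the values were already equal between arrays, and the deposited normalized values, planned as an alternative, are the input. With background correction, offset or scaling changed, the share of genes at unadjusted p 0.05 that were higher in PyMT/ETP ran from 46.6% to 48.7%, against 52.8%. Without background correction at the stricter limit, which also changed the genes tested, the share was 45.7%. Signal over background limits the higher named genes, most of which lay near 4.61 log2 units.

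Of 2123 comparisons of 129 named genes with an alternative, 29 turned the sign, and 2094 kept it, with none passing. Of 492 comparisons of lists, 399 kept the direction and the side of the threshold, 27 lost the call, 29 gained it and 37 turned the sign. With 1 array left out, list medians ran from -0.13 to 0.27 for fibrillar collagen, -0.041 to 0.047 for basement membrane, -0.15 to 0.042 for mesenchymal markers, -0.16 to 0.060 for TGF-beta, -0.048 to 0.14 for endothelial genes, -0.31 to 0.025 for neutrophils, -0.18 to 0.035 for lymphocytes, -0.13 to 0.047 for chemokines, -0.27 to 0.12 for adipocytes, -0.051 to 0.11 for cell cycle, -0.39 to 0.053 for hypoxia, -0.0073 to 0.14 for the unfolded protein response, -0.21 to -0.0081 for immediate early genes, -0.52 to -0.0045 for red blood cells and -0.028 to 0.37 for skeletal muscle. The interferon list ran from -0.39 to 0.32, the highest without PyMT/ETP replicate 1, where it was called at the preset correlation with an adjusted p of 0.000506 (adjusted p = 0.676 with an estimated correlation). Gene differences ran from -0.19 to 0.13 for Col6a2, -0.17 to 0.21 for Col6a1, -0.019 to 0.67 for Col1a2, -0.43 to 0.021 for Ddx58, -0.25 to 0.046 for Gata3, -0.57 to 0.060 for Hbb-bt and -0.12 to 0.035 for Rpl3. With the mean of all probes, Zeb2 was at -0.086, Esr1 at -0.0038 and Actn3 at 0.10. With no low-value filter the lymphocyte list was at 0.080.

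Without PyMT control replicates 2 and 3, these medians turned: basement membrane 0.057, TGF-beta 0.095, neutrophils 0.080, lymphocytes 0.0093, chemokines 0.016, adipocytes 0.40, unfolded protein response -0.11, red blood cells 0.016 and ribosomal proteins 0.037. The genes that turned were Col6a2 (0.18), Id1 (0.095), Tgfbr2 (-0.019), S100a8 (0.086), Ccr7 (0.16), Zbp1 (-0.15), Lpl (0.43), Csn1s1 (0.073), Krt17 (0.19), P4ha2 (0.048), Elovl1 (0.018), Atf3 (0.060), Fosb (0.070), Hbb-bt (0.075) and Rpl3 (0.016). The cause of these turns was not tested.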

Other observations

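The one-array tests of the basal and the macrophage list were chosen after the results were seen, and the genes named in this part were chosen after their values were seen. Many genes differed widely between tumours of one group. The first principal component held 33.2% of the variance and the second 23.5%, and the mean correlation of array pairs was 0.984 within groups and 0.983 between them. The hypoxia and glycolysis list deviated by -0.63 in PyMT/ETP replicate 1, -0.29 in replicate 2 and 0.67 in replicate 3. Vegfa, the main angiogenic growth factor, was at 8.82, 9.98 and 12.28 in those tumours and between 10.54 and 10.81 in the controls. Ndrg1 was at 10.09, 10.16 and 12.06, and Adm at 4.73, 6.01 and 8.35. The interferon list deviated by -0.87 in PyMT/ETP replicate 1 and 0.36 and 0.31 in the other PyMT/ETP tumours. There, Rsad2 was at 6.62 against 9.01 and 9.06, and Usp18 at 6.14 against 8.45 and 8.58.

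The caseins Csn2 and Csn1s1 were at 12.89 and 12.74 in PyMT control replicate 3, and in the other 5 tumours Csn2 lay between 9.63 and 10.42 and Csn1s1 between 10.16 and 10.73. Skeletal muscle genes deviated by 0.45 in PyMT/ETP replicate 1, where Acta1 was at 9.56 and Myl1 at 8.94. The imprinted gene Mest was at 8.74 and 8.28 in PyMT/ETP replicates 1 and 2 and at 6.76 in replicate 3, against 6.27 to 6.66 in controls. Hoxa5 was at 7.71, 7.25 and 5.50 in those tumours, against 5.19 to 5.91 in controls.

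Hair genes were high in PyMT control replicates 2 and 3, and the skin keratinocyte list in replicate 3 (1.29, against 0.15 in replicate 2). The hair shaft and inner root sheath list, some of whose genes had been seen to vary before it was written, deviated by 1.37 and 2.03 there and by -0.79 to -0.88 in the other 4 tumours. Krt73 was at 9.13 and 10.16 against at most 4.99, and Krt34 at 8.94 and 8.45 against at most 4.75. Some keratinocyte genes outside the skin keratinocyte list were also high in both replicates. Cdsn was at 8.30 and 8.87 against at most 5.11, and Crct1 at 9.12 and 10.55 against at most 5.67. Within that list of 5 measured genes, 3 were highest in replicate 3, and Lor was highest in replicate 2 (6.40, against 5.63 in replicate 3). A candidate explanation for the higher skin keratinocyte genes of PyMT control replicate 3 is skin carried into the sample, which would bring every skin cell type. The sebaceous gland list of 6 measured genes exceeded the highest other array by only 0.003 (SE 0.375), with deviations of 0.27 in both PyMT control replicates 2 and 3 and 0.20 in PyMT/ETP replicate 1, and the melanocyte list by -0.001. In the sebaceous list, 3 of 6 genes were highest in PyMT control replicate 3. Among them were the bright Krt79 (9.70, against at most 8.805) and Plin2 (10.16, against at most 9.82). In the melanocyte list, 2 of 5 genes were, and Sox10 was at 12.07 to 12.49 in all 6 tumours. Both lists were mostly near background, so skin cannot be told apart from keratinised or hair-like differentiation of the tumour itself, which was not tested.

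Keratinocyte keratins of PyMT control replicate 3 may account for the lower basal and myoepithelial list, or the list may differ between the groups. Without that array the mean difference was -0.214 (SE 0.24), against -0.315 with all arrays. The array was picked because it stood out, so a smaller difference without it follows from its value, and the test could only have argued against the explanation, which it did not. The 3 keratins of the list averaged -0.691 and the 7 other members -0.154. Replicate 3 is not alone in this: Krt17, the keratin with the largest difference, was at 11.65 in PyMT control replicate 2, 11.52 in replicate 3 and 9.64 in replicate 1. Its difference was -0.81 without replicate 3 and 0.19 without replicates 2 and 3.

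The macrophage list was tested in the same way, with the same limit. Its deviation was highest in PyMT/ETP replicate 1, and without that array the mean difference was 0.039 (SE 0.048), against 0.136 with all arrays. This restates that array's value, and whether the list differs between the groups or only in that tumour stays open.

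The 6 tumours can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. All 10 gave 0 genes past adjusted p 0.05, the highest other being 0. For genes at unadjusted p 0.05, 6 of the 10 splits, the real one included, reached 555, and the highest other gave 921. For gene lists, 9 of the 10, the real one included, reached 4, and the highest other, which set PyMT control replicates 1 and 2 with PyMT/ETP replicate 3 against the rest, gave 11.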
